A study of Mus musculus with 11 samples.

How the data were processed

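RNA from the rectal mucosa of 11 mice, 10 weeks old, was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per mouse. Per the labels, tamoxifen at 10 mg per day or NaCl was given by gavage every other day over 5 days from the age of 8 weeks, and the tissue was taken 15 days after the first gavage. The authors deposited 1 value per transcript cluster and array, on the log2 scale, and per the labels made in Affymetrix Expression Console with RMA, a method that corrects background, quantile-normalises arrays and summarises probes. Per the series design text the images were read with Command Console version 2.0 and the values made with Expression Console version 1.1. The submitters' processing notes also name Partek, without its role. Tests and thresholds used by the authors, and a genome build, are not given in the sources used here, and no coordinates are reported.

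The table held 35556 transcript clusters. The platform annotation listed 23410 of them, 21797 with 1 gene symbol and 1613 with several, and 12146 were not listed and are unnamed here. Symbols were brought up to date with a RefSeq gene table of the mouse assembly GRCm38.p6, used for names alone: 21701 matched as they were, 2 were updated, 5 of the matches were made by accession, and 94 had no match and kept the annotation's symbol. For the 1001 genes with several transcript clusters, the cluster with the highest mean over all arrays was used, which gave 19944 genes, and no filter on dim genes was applied. Transcript clusters without exactly 1 symbol were left out of the comparisons.

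Groups were taken from the genotype and treatment in the labels: mutant tamoxifen (n = 4), control tamoxifen (n = 3) and mutant NaCl (n = 4). In single-array names these are mutant_tam, control_tam and mutant_nacl, with replicate numbers that only name an array. All 11 arrays were fitted in 1 linear model per gene with limma version 3.58.1 in R version 4.3.3, with a term for sex because the sexes are unevenly spread over the groups, and moderated variances with a trend on the mean level. The contrasts were each mutant group against control tamoxifen, mutant tamoxifen against mutant NaCl, and mutant tamoxifen against the mean of both reference groups, and the sex term was tested as male minus female. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on adjusted p. Differences are on the log2 scale and folds are 2 to the power of their size, so a fold given for a decrease is the factor by which the gene was lower. Groups of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 34 lists. Of these, 19 name pathways or epithelial functions and 15 name cell types, including cells other than epithelium that the mucosa samples can hold. The lists hold 546 genes measured here, of which 12 are in more than 1 list. An estimated correlation and limma's fry, which tests whether a list's genes move one way on balance, were run beside it. Counts of members past the threshold are given over all genes and adjusted over the list alone.

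The groups, tests, lists, named genes and processing alternatives were fixed before the data were examined, except where the text says otherwise. The named genes were Itga6 and, for each comparison of the mutant tamoxifen group with 1 other group, the 12 genes with the largest increase and the 8 with the largest decrease. They had to be past the threshold with all values of one group above those of the other. For mutant NaCl against control tamoxifen, where fewer than 5 genes passed, the 10 genes with the smallest p are given. Predicted genes, immunoglobulin and T cell receptor segments, olfactory and vomeronasal receptors, small RNA genes and sex-linked genes were left out of this rule. For each list, at most the 4 members with the smallest p were named.

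The comparisons against control tamoxifen and against mutant NaCl share the mutant tamoxifen arrays. Their overlap is therefore given with 100 simulations of unchanged groups, with the overlap of independent lists, and with the shared arrays divided between the comparisons in all 6 ways. The steps were tested on simulated data in which 100 genes per size were changed among 19944. For mutant tamoxifen against control tamoxifen, 100% of genes changed by a log2 difference of 1 and 94% of those changed by 0.5 were called, with 14 unchanged genes called. Against mutant NaCl the shares were 100% and 95%, against both reference groups 100% and 98%, and for mutant NaCl against control tamoxifen 99% and 96%. With the proliferation list alone shifted, camera called 2 lists for mutant tamoxifen against control tamoxifen, so a list that was not shifted was called as well.

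Alternatives tried were no sex term, female arrays alone, only the arrays of the groups compared, leaving out the lowest 25% or 50% of genes by mean level, centring arrays on their median and a second quantile normalisation. Further ones were no variance trend, an ordinary linear model without moderation, array weights, the mean of a gene's transcript clusters, all transcript clusters, at least 1.5-fold as well, and leaving out each array in turn. After seeing the data, the mean level of squamous epithelium markers was added as a term, and a fit with 1 control array was run. Other divisions of the arrays were counted for each comparison, in full where there were 35 and over 100 draws otherwise, the real one included.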

Results

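Gene expression was measured in the rectal mucosa of 11 mice, 1 array per animal, on Affymetrix Mouse Gene 1.0 ST arrays, which measure transcripts with probes spread along their length. The mutant mice carry an Itga6 gene that tamoxifen given by gavage is meant to delete in the intestinal epithelium. Itga6 encodes integrin α6, which pairs with integrin β4 in hemidesmosomes, the junctions that tie the basal side of an epithelial cell to laminin in the basement membrane. There were 4 mutant mice given tamoxifen, 3 wild-type control mice given tamoxifen and 4 mutant mice given NaCl in its place. The mice were 10 weeks old and were analysed 15 days after the first gavage. In the mutant groups 1 of 4 animals was male, and in the control group 2 of 3 were. Each array gave 35556 transcript clusters, with medians on the log2 scale between 7.29 and 7.35, and 19944 genes were tested. Correlations between arrays of a group were 0.988 to 0.997, and the lowest correlation between arrays of different groups was 0.977. Xist and 3 Y-linked genes separated the arrays by the sexes in the labels. The first principal component held 47.0% of the variance, and the 4 arrays labelled mutant tamoxifen lay at 22.0 to 25.4 on it, apart from the 7 others at -29.1 to -8.14. P-values of single genes measure the spread between these animals, whose number limits the precision. List p-values with the preset correlation compare a list's genes with all others. They do not measure how the members vary together between animals.

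The targeted gene went against its label. Itga6 (Entrez Gene 16403) had log2 levels of 11.75, 11.93, 11.84 and 11.77 in the arrays labelled mutant tamoxifen, with a mean of 11.82 ± 0.0782 (SD, n = 4). In the control tamoxifen arrays the levels were 11.15, 11.52 and 11.49 (mean 11.39 ± 0.204, SD, n = 3), and in the mutant NaCl arrays 11.39, 11.28, 11.49 and 11.47 (mean 11.41 ± 0.0937, SD, n = 4). Where a deletion would lower the gene, its signal was 1.34-fold higher than in the control arrays (limma, log2 difference 0.42, SE 0.096, adjusted p = 0.00949, 95% confidence interval 0.21 to 0.64). It was 1.33-fold higher than in the mutant NaCl arrays (limma, log2 difference 0.41, SE 0.083, adjusted p = 0.0053, interval 0.23 to 0.60). Mutant NaCl and control arrays differed by 0.01 (adjusted p = 0.987). Itga6 is read by 1 transcript cluster, and whether its probes lie in the deleted part is not known here, so the signal does not check the labels. Cells other than epithelial cells also express the gene. Without mutant_tam replicate 3, the male of that group, the difference from the control arrays was 0.40 and no longer past the threshold. For these reasons the group is named by its label throughout.

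**Figure D1:**
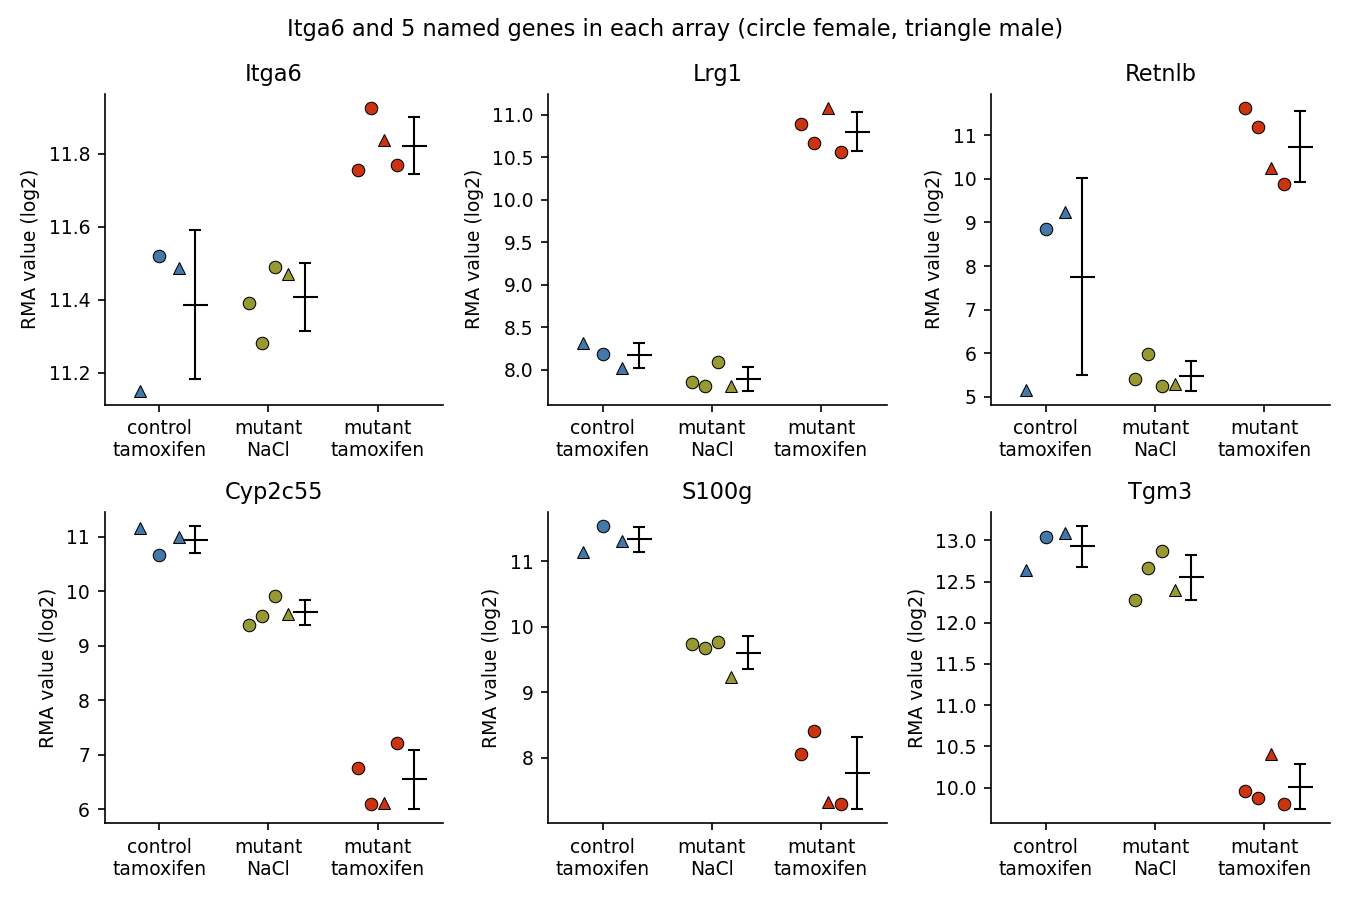
Log2 expression of Itga6, Lrg1, Retnlb, Cyp2c55, S100g and Tgm3 in each of the 11 arrays, with circles for female and triangles for male mice and a bar for the group mean with its SD. Itga6 lies at 11.75 to 11.93 in the arrays labelled mutant tamoxifen and at 11.15 to 11.52 in the others, and Lrg1 is separated in the same direction while Cyp2c55 and S100g are lowest in that group.

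The comparison of mutant with control mice, both given tamoxifen, asks what differs with the mutant genotype once the drug is the same. The arrays labelled mutant tamoxifen had lower levels of the transport and enzyme genes of the absorptive colonocyte, and higher levels of genes of antimicrobial defence, epithelial repair and cell division. With an estimated correlation the absorptive colonocyte list kept its call (adjusted p = 0.00668), and the lists of defence, repair and division lost theirs (adjusted p = 0.245 for each). With fry, which does not compare a list with the other genes, defence, repair and division passed (adjusted p = 0.00336, 0.00148 and 0.00425). Cyp2c55, a cytochrome P450 that oxidises arachidonic acid, was 21.6-fold lower, and Lrg1, a secreted glycoprotein of the acute phase response, was 6.34-fold higher. The proliferation list, also higher in mutant NaCl than in the control arrays (median log2 difference 0.38), had all 29 measured genes higher here. Of 25 absorptive colonocyte genes measured 18 fell. With limma, 2570 genes were higher and 2345 lower among 19944, which is 24.6% of the genes tested. At least 1.5-fold apart were 530 of the higher and 387 of the lower genes, and at least 2-fold apart 133 and 95. Signs follow the group labels, against which Itga6 went.

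Several of the genes with the largest increases act in defence or inflammation. Lrg1 rose with the smallest error of the 12 (log2 difference 2.67, SE 0.13, adjusted p = 2.72e-06). Pla2g2a, a secreted phospholipase A2 that kills Gram-positive bacteria, rose as well (log2 difference 2.84, SE 0.23, adjusted p = 6.29e-05). Retnlb, the goblet cell protein RELMβ, was 6.24-fold higher (log2 difference 2.64, SE 0.83), close to the threshold (adjusted p = 0.0402), and the control arrays read 5.17, 8.86 and 9.24. Ppbp, a platelet chemokine, was 6.02-fold higher (adjusted p = 0.0359), and AI506816 5.62-fold higher (adjusted p = 0.046). Other genes with large increases encode enzymes and transporters. Dhrs9, a dehydrogenase that acts on retinol, was 7.71-fold higher (log2 difference 2.95, SE 0.32, adjusted p = 0.000272), and Mfsd2a, which carries lysophosphatidylcholine into cells, 7.2-fold higher (log2 difference 2.85, SE 0.30, adjusted p = 0.000227). Cwh43, which takes part in the remodelling of glycosylphosphatidylinositol anchors, rose 6.58-fold (adjusted p = 1.75e-05), and Ddah1, which degrades an inhibitor of nitric oxide synthases, 5.11-fold (adjusted p = 8.19e-05). The cell surface protein gene Plet1 (6.15-fold, adjusted p = 0.00229), the glycosyltransferase gene Mgat4c (5.53-fold, adjusted p = 0.00118) and Trim15 (5.39-fold, adjusted p = 1.75e-05) complete the 12.

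Among the genes with the largest decreases were carriers of calcium and phosphate. S100g, the cytosolic calcium-binding protein calbindin-D9k, was 13.5-fold lower (log2 difference -3.76, SE 0.21, adjusted p = 6.08e-06). Trpv6, the calcium channel of the apical membrane, was 4.99-fold lower (log2 difference -2.32, SE 0.32, adjusted p = 0.000958), and Slc34a2, a sodium-phosphate cotransporter, 5.36-fold lower (log2 difference -2.42, SE 0.34, adjusted p = 0.000965). Cyp2c55 fell most (log2 difference -4.43, SE 0.27, adjusted p = 1.01e-05). A further cytochrome P450 gene, Cyp2d12, was 8.22-fold lower (adjusted p = 4.57e-06), Tgm3, a transglutaminase that crosslinks proteins, 7.42-fold lower (adjusted p = 1.73e-05) and Naaladl1, a peptidase gene, 5.59-fold lower (adjusted p = 3.89e-06). St8sia5, a sialyltransferase gene, was 5.2-fold lower (adjusted p = 0.0107). In mutant NaCl, S100g and Slc34a2 also read lower than in control tamoxifen (log2 differences -1.93 and -1.95), neither past the threshold. Slc34a2 and St8sia5 did not pass in mutant tamoxifen against mutant NaCl (limma, log2 differences -0.47 and -0.99, adjusted p = 0.296 and 0.172).

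Of epithelial lists, the absorptive colonocyte list fell (median log2 difference -0.69, adjusted p = 2.15e-10, and adjusted p = 0.00668 with an estimated correlation). Of its 25 measured members, 18 fell and 2 rose over all genes, and 20 fell and 2 rose when adjusted over the list alone. Slc26a3, the apical chloride-bicarbonate exchanger, fell (log2 difference -1.67, 3.18-fold, adjusted p = 2.65e-06), as did the carbonic anhydrase genes Car4 (log2 difference -1.24, 2.36-fold, adjusted p = 3.27e-06) and Car2 (log2 difference -1.11, 2.16-fold, adjusted p = 6.38e-06). The antimicrobial and epithelial defence list rose (median log2 difference 0.60, adjusted p = 0.000291, and adjusted p = 0.245 with an estimated correlation). There 15 of 28 members rose and 1 fell, or 17 and 3 adjusted over the list alone. Saa3, a serum amyloid A (log2 difference 2.32, 4.99-fold, adjusted p = 2.17e-05), Slpi, a protease inhibitor (log2 difference 1.65, 3.13-fold, adjusted p = 0.00197), and Lcn2, which withholds iron from bacteria (log2 difference 1.18, 2.27-fold, adjusted p = 0.00512), were among them. Wound and regenerative epithelium genes rose too (median log2 difference 0.56, adjusted p = 6.63e-06, and adjusted p = 0.245 with an estimated correlation), with 13 of 17 higher and 0 lower over all genes, and 13 higher and 2 lower adjusted over the list alone. Mmp7 (matrilysin, log2 difference 2.32, 5.01-fold, adjusted p = 9.82e-05), Mmp10 (log2 difference 1.38, 2.61-fold, adjusted p = 0.000882) and Sprr2h (log2 difference 1.32, 2.5-fold, adjusted p = 0.000106) led that list. Beside these groups, in the same arrays, neutrophil markers were higher (median 0.65) and smooth muscle markers lower (median -0.49). S100a8 and S100a9 are on both the antimicrobial and the neutrophil list, and which cells of the mucosa these lists were read from was not tested.

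Genes of cell division rose as a group. All 29 measured proliferation genes were higher over all genes and adjusted over the list alone (median log2 difference 0.81, adjusted p = 1.76e-16, and adjusted p = 0.245 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase (log2 difference 1.29, 2.45-fold, adjusted p = 0.000386), Mcm5, part of the replicative helicase (log2 difference 0.85, 1.8-fold, adjusted p = 0.00137), and the mitotic kinase gene Cdk1 (log2 difference 0.89, 1.85-fold, adjusted p = 0.0017) were examples. The mean level of the list was 8.73, 9.12 and 9.37 in the control arrays and 9.33 to 9.58 in mutant NaCl. It was 9.79 to 9.96 in the arrays labelled mutant tamoxifen. As a group, mutant NaCl thus also lay above control tamoxifen (median log2 difference 0.38), with 0 members past the threshold over all genes. The unfolded protein response list rose (median log2 difference 0.29, adjusted p = 0.000176, and adjusted p = 0.361 with an estimated correlation), with 11 of 20 members higher, or 14 adjusted over the list alone, among them Manf (log2 difference 0.41, 1.33-fold, adjusted p = 0.00342). Simple keratins and cell junctions rose (median log2 difference 0.14, adjusted p = 0.000441, and adjusted p = 0.245 with an estimated correlation), with 9 of 25 higher and 1 lower, or 11 and 1 adjusted over the list alone. Krt7 (log2 difference 1.13, 2.19-fold, adjusted p = 0.000158), Krt18 (log2 difference 0.38, 1.3-fold, adjusted p = 0.000722) and the desmosomal cadherin gene Dsc2 (log2 difference 0.75, 1.68-fold, adjusted p = 0.000123) were higher. In the hemidesmosome and laminin adhesion list (median log2 difference 0.11, adjusted p = 0.0186, and adjusted p = 0.601 with an estimated correlation), 7 of 17 members rose and 2 fell, with the same numbers adjusted over the list alone. Itgb4, which encodes the partner of integrin α6, rose (log2 difference 0.51, 1.43-fold, adjusted p = 0.000965), as did Plec, its cytoskeletal linker (log2 difference 0.51, 1.43-fold, adjusted p = 0.00235), and Itga3, another laminin-binding integrin (log2 difference 0.43, 1.35-fold, adjusted p = 0.00232). The hemidesmosome list lost its call in 8 of 26 settings. Beside the estimated correlation these were fits without control_tam replicate 3 (median 0.08) or mutant_nacl replicate 4 (0.10), fry (adjusted p = 0.0611), quantile normalisation again, 1 control array, and the lowest 25% or 50% of genes left out, and its median was 0.18 without mutant_tam replicate 3. Smooth muscle markers were lower in this comparison (median -0.49). Whether a smaller share of muscle bears on the keratin and hemidesmosome lists was not tested.

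Inflammatory genes and markers of other cell types moved in the same arrays. Neutrophil markers rose (median log2 difference 0.65, adjusted p = 1.16e-06, and adjusted p = 0.245 with an estimated correlation), with 10 of 12 higher, or 11 adjusted over the list alone. Csf3r, the receptor of granulocyte colony-stimulating factor (log2 difference 0.91, 1.88-fold, adjusted p = 0.000434), and Il1b, which encodes interleukin 1β (log2 difference 2.32, 5.01-fold, adjusted p = 0.00114), were higher. Chemokines and NF-kB targets rose (median log2 difference 0.14, adjusted p = 0.0186, and adjusted p = 0.245 with an estimated correlation), with 8 of 24 higher and 1 lower, and the same numbers adjusted over the list alone, led by the neutrophil attractant Cxcl5 (log2 difference 2.08, 4.23-fold, adjusted p = 0.000113). The inflammasome and IL-1 family list rose (median log2 difference 0.12, adjusted p = 0.0172, and adjusted p = 0.245 with an estimated correlation), although 3 of its 19 members rose and 1 fell, also adjusted over the list alone, and Il1b and Il33 (log2 difference 0.60, 1.52-fold, adjusted p = 0.00421) were the larger ones. Its call was lost in 6 of 26 settings, which beside the estimated correlation were female arrays alone, the lowest 25% or 50% of genes left out, a squamous marker term and 1 control array. Il1b is also on the neutrophil list, and 24.6% of all genes passed in this comparison. Matrix and remodelling genes rose (median log2 difference 0.27, adjusted p = 0.00126, and adjusted p = 0.582 with an estimated correlation), with 7 of 23 higher and 1 lower, or 9 and 1 adjusted over the list alone. Timp1, an inhibitor of metalloproteinases (log2 difference 1.23, 2.34-fold, adjusted p = 0.000216), and Mmp3 (log2 difference 0.99, 1.99-fold, adjusted p = 0.000262) led it. The matrix list lost its call with fry (adjusted p = 0.0567), and the chemokine list without control_tam replicate 2 (median 0.10).

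All 12 smooth muscle markers fell, over all genes and adjusted over the list alone (median log2 difference -0.49, adjusted p = 4.19e-09, and adjusted p = 0.245 with an estimated correlation). Pcp4 (log2 difference -0.89, 1.85-fold, adjusted p = 0.000166), Cnn1 (log2 difference -0.45, 1.37-fold, adjusted p = 0.000414) and Tagln (log2 difference -0.53, 1.44-fold, adjusted p = 0.000881), which bind calmodulin or actin, were lower. The mean level of these markers was 11.54 to 11.68 in the arrays labelled mutant tamoxifen and 11.98 to 12.25 in all others. Enteric neuron and glia markers fell (median log2 difference -0.24, adjusted p = 0.00389, and adjusted p = 0.245 with an estimated correlation), with 5 of 11 lower, or 7 lower and 1 higher adjusted over the list alone, such as Stmn2 (log2 difference -0.79, 1.73-fold, adjusted p = 0.00115). The median of this list was -0.39 to -0.19 over the other settings. Plasma cell markers rose (median log2 difference 0.30, adjusted p = 0.0121, and adjusted p = 0.582 with an estimated correlation), with 3 of 10 higher, also adjusted over the list alone. These were Prdm1 (log2 difference 0.77, 1.71-fold, adjusted p = 0.000577), Sdc1 and Fkbp11, and epithelial cells also express Sdc1. Macrophage and dendritic cell markers fell (median log2 difference -0.25, adjusted p = 0.013, and adjusted p = 0.582 with an estimated correlation), with 5 of 15 lower, or 6 adjusted over the list alone. The plasma cell list was not past the threshold with fry (adjusted p = 0.0928) or without control_tam replicate 2 (median -0.04). The macrophage list was not past it with fry (adjusted p = 0.055), female arrays alone, 1 control array or without control_tam replicate 3 (-0.14), and its median was -0.41 without control_tam replicate 2.

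The other 19 of the 34 lists did not pass in this comparison. Members moved both ways in the goblet cell and mucus list (7 of 22 higher, 4 lower, adjusted p = 0.307), the stem cell and Wnt target list (3 of 19 higher, 5 lower, adjusted p = 0.694) and the enteroendocrine list (3 of 18 higher, 3 lower, adjusted p = 0.783). Xenobiotic and oestrogen response genes gave 1 of 18 higher and 6 lower (adjusted p = 0.337), with Ces2a, a carboxylesterase gene, lower (log2 difference -1.43, 2.69-fold, adjusted p = 0.000259). Adjusted p was 0.185 for tuft cell, 0.919 for the IL-17 and IL-22 axis, 0.118 for type 2 immunity, 0.694 for interferon and antigen presentation and 0.608 for p53 and apoptosis genes. Among cell types it was 0.107 for stratified squamous epithelium, 0.107 for fibroblast, 0.964 for endothelial, 0.676 for T cell and NK cell, 0.333 for B cell and 0.388 for eosinophil markers. It was 0.279 for mast cell, 0.691 for adipocyte, 0.656 for red blood cell (2 of 8 genes measured) and 0.121 for skeletal muscle markers. The median and mean had opposite signs in the p53 list (-0.08 and 0.04, test up), the IL-17 and IL-22 list (-0.02 and 0.06, test up) and the endothelial list (0.04 and -0.04, test down).

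Of the 15 lists past the threshold with the preset correlation of 0.01, the absorptive colonocyte list also passed with an estimated correlation, and 7 of the 35 ways to divide these 7 arrays into groups of 4 and 3, the real one included, gave at least 15 list calls. With the lowest 50% of genes left out, the keratin, wound, matrix, neutrophil, chemokine and plasma cell lists also lost their calls, the chemokine list with the lowest 25% left out as well. The squamous marker term and the fit with 1 control array were chosen after seeing the data. The number of genes called was 2517 without mutant_tam replicate 3 and 3031 without control_tam replicate 2. Centring each array on its median gave 3016 genes higher and 1808 lower, against 2570 and 2345.

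Calls of 4 genes with wide spread ended when single arrays were left out. Retnlb was not past the threshold without any 1 of mutant_tam replicates 1, 2 and 3 (differences 2.45, 2.57 and 2.54), control_tam replicate 2 (3.20) or mutant_nacl replicates 1 to 4 (2.62, 2.66, 2.61 and 2.51), and its difference was 1.63 without control_tam replicate 1. Ppbp was not past it without any 1 of mutant_tam replicates 1 to 4 (2.69, 2.59, 2.50 and 2.51), control_tam replicates 1 and 3 (1.96 and 2.47) or mutant_nacl replicate 2 (2.59), and read 4.30 without control_tam replicate 2. AI506816 was not past it without any 1 of mutant_tam replicates 1 to 4 (2.38, 2.44, 3.18 and 2.41), control_tam replicates 1 and 2 (1.90 and 2.72) or mutant_nacl replicates 3 and 4 (2.42 and 2.18). St8sia5 was not past it without control_tam replicate 2 (-2.08).

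Within the mutant genotype, the comparison of tamoxifen with NaCl asks what differs with the gavage meant to induce the deletion. Again the arrays labelled mutant tamoxifen had lower absorptive colonocyte genes and higher defence, repair and division genes. With an estimated correlation the call of the absorptive list was kept (adjusted p = 0.00391), and those of the lists of defence, repair and division were lost (adjusted p = 0.209, 0.209 and 0.438). With fry, defence, repair and division passed (adjusted p = 0.000837, 0.000685 and 0.027). Retnlb was 38.2-fold higher than in the mutant NaCl arrays, where its level was 5.24 to 5.98, and Cyp2c55 was 8.35-fold lower. In the control tamoxifen arrays Retnlb read 5.17, 8.86 and 9.24, so its level was also high in some mice without the deletion. All 12 smooth muscle markers fell and 11 of 12 neutrophil markers rose. Of 26 interferon and antigen presentation genes, 11 were lower and 1 higher. Their list lost its call with an estimated correlation (adjusted p = 0.498) and with fry (adjusted p = 0.0584), and did not pass against the control arrays. The difference between the comparisons is itself that of mutant NaCl from control tamoxifen, in which 0 genes passed (limma, 1625 at an unadjusted p under 0.05 and 0 to 3 past the threshold in other settings). There the interferon list was higher in mutant NaCl (camera, median log2 difference 0.53, adjusted p = 1.02e-14, and adjusted p = 0.814 with an estimated correlation). With limma, 2498 genes were higher and 2136 lower in mutant tamoxifen than in mutant NaCl, which is 23.2% of the genes tested, and 334 in each direction were at least 1.5-fold apart. Centring each array on its median gave 2868 higher and 1815 lower. Signs again follow the labels, against which Itga6 went.

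Of the 12 genes with the largest increases, several take part in defence or inflammation. Retnlb (log2 difference 5.26, SE 0.72, adjusted p = 0.000746), Pla2g2a (log2 difference 3.22, SE 0.20, adjusted p = 1.02e-05) and Lrg1 (log2 difference 2.91, SE 0.11, adjusted p = 7.26e-07) rose. Saa3 was 5.82-fold higher (adjusted p = 4.97e-06), Mmp7 5.63-fold (adjusted p = 2.02e-05) and Il1b 4.49-fold (adjusted p = 0.000684). Cwh43 (7.54-fold, adjusted p = 4.21e-06), Ddah1 (5.93-fold, adjusted p = 1.56e-05), Mfsd2a (5.36-fold, adjusted p = 0.000189), Mgat4c (4.99-fold, adjusted p = 0.000695), Trim15 (4.61-fold, adjusted p = 1.03e-05) and Dhrs9 (4.54-fold, adjusted p = 0.000501) were the others. Among the 8 with the largest decreases, Cyp2c55 (log2 difference -3.06, SE 0.24, adjusted p = 2.81e-05), Tgm3 (5.81-fold, adjusted p = 1.18e-05), Naaladl1 (5.24-fold, adjusted p = 1.19e-06) and Cyp2d12 (5.22-fold, adjusted p = 7.69e-06) were also on the list against the control arrays. Slc4a4, a sodium-bicarbonate cotransporter (log2 difference -2.11, SE 0.096, adjusted p = 9.67e-07), Dio1, a deiodinase of thyroid hormone (log2 difference -2.27, SE 0.19, adjusted p = 4.19e-05), and Retnla, which encodes RELMα (log2 difference -2.14, SE 0.33, adjusted p = 0.00145), fell. Krtap15, a keratin-associated protein gene, was lower (log2 difference -2.17, adjusted p = 0.0482). Its call ended without any 1 of mutant_tam replicates 1 to 4 (-2.26, -2.29, -1.68 and -2.27), mutant_nacl replicates 1, 2 and 4 (-1.97, -2.44 and -1.16) or control_tam replicates 1 and 3 (-2.17 for each).

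Epithelial lists moved as follows. The absorptive colonocyte list fell (median log2 difference -0.73, adjusted p = 5.67e-12, and adjusted p = 0.00391 with an estimated correlation), with 19 of 25 lower and 2 higher, or 20 and 2 adjusted over the list alone, and Slc26a2, a sulfate transporter gene, fell (log2 difference -1.06, 2.09-fold, adjusted p = 2.02e-05). The antimicrobial list rose (median log2 difference 0.78, adjusted p = 1.78e-05, and adjusted p = 0.209 with an estimated correlation), with 15 of 28 higher and 1 lower, or 18 and 2 adjusted over the list alone, and Reg4 rose (log2 difference 0.86, 1.82-fold, adjusted p = 0.000393). Wound and regenerative genes rose (median log2 difference 0.62, adjusted p = 4.4e-06, and adjusted p = 0.209 with an estimated correlation), with 12 of 17 higher and 0 lower, or 12 and 1 adjusted over the list alone, and Mmp10 rose (log2 difference 1.41, 2.66-fold, adjusted p = 0.000316). Proliferation genes rose (median log2 difference 0.49, adjusted p = 2.09e-09, and adjusted p = 0.438 with an estimated correlation), with 20 of 29 higher, or 22 adjusted over the list alone, among them Rrm2 (log2 difference 0.83, 1.78-fold, adjusted p = 0.00148) and Mcm6 (log2 difference 0.63, 1.55-fold, adjusted p = 0.00427). The unfolded protein response list rose (median log2 difference 0.24, adjusted p = 7.34e-05, and adjusted p = 0.417 with an estimated correlation), with 11 of 20 higher, or 15 higher and 1 lower adjusted over the list alone, such as Asns, asparagine synthetase (log2 difference 0.89, 1.85-fold, adjusted p = 0.00756). Simple keratins and cell junctions rose (median log2 difference 0.13, adjusted p = 7.34e-05, and adjusted p = 0.26 with an estimated correlation), with 12 of 25 higher and 1 lower, or 13 and 1 adjusted over the list alone, such as Krt7 (log2 difference 1.37, 2.59-fold, adjusted p = 1.69e-05) and Cldn4 (log2 difference 1.33, 2.52-fold, adjusted p = 0.000935). Hemidesmosome and laminin genes rose (median log2 difference 0.17, adjusted p = 0.0115, and adjusted p = 0.498 with an estimated correlation), with 7 of 17 higher and 3 lower, also adjusted over the list alone. Lamb3 (log2 difference 0.77, 1.7-fold, adjusted p = 0.00021) and Lama3 (log2 difference 0.82, 1.77-fold, adjusted p = 0.000849), which encode laminin chains, and Itgb4 (log2 difference 0.51, 1.43-fold, adjusted p = 0.000376) rose. Goblet cell and mucus genes rose (median log2 difference 0.15, adjusted p = 0.0121, and adjusted p = 0.498 with an estimated correlation), with 8 of 22 higher and 3 lower, or 11 and 5 adjusted over the list alone, although the list was not past the threshold without mutant_tam replicate 1 (median 0.09). Spink4 (log2 difference 0.82, 1.77-fold, adjusted p = 0.000158) and Galnt12 (log2 difference 0.80, 1.74-fold, adjusted p = 3.83e-05), a protease inhibitor and a mucin-type glycosyltransferase, were examples. In the same arrays neutrophil markers were higher (median 0.78) and smooth muscle markers lower (median -0.47).

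Among immune genes, the neutrophil markers rose (median log2 difference 0.78, adjusted p = 7.47e-09, and adjusted p = 0.209 with an estimated correlation), with 11 of 12 higher over all genes and adjusted over the list alone, among them Retnlg (log2 difference 1.00, 1.99-fold, adjusted p = 0.000579). Chemokines and NF-kB targets rose (median log2 difference 0.13, adjusted p = 0.0121, and adjusted p = 0.209 with an estimated correlation), with 8 of 24 higher and 1 lower, or 8 and 2 adjusted over the list alone, led by Cxcl5 (log2 difference 1.93, 3.82-fold, adjusted p = 5.22e-05) and Cxcl2 (log2 difference 1.92, 3.78-fold, adjusted p = 0.00313). Interferon and antigen presentation genes fell (median log2 difference -0.50, adjusted p = 5.99e-05, and adjusted p = 0.498 with an estimated correlation), with 11 of 26 lower and 1 higher, or 13 and 1 adjusted over the list alone. H2-Aa (log2 difference -1.18, 2.27-fold, adjusted p = 0.00174), H2-Ab1 (log2 difference -1.14, 2.2-fold, adjusted p = 0.00694) and Cd74 (log2 difference -0.89, 1.85-fold, adjusted p = 0.00439), which serve antigen presentation on MHC class II, were lower. This list and the B cell list were highest in mutant_nacl replicate 1, with mean levels of 9.77 and 9.15. Plasma cell markers rose (median log2 difference 0.18, adjusted p = 0.0121, and adjusted p = 0.498 with an estimated correlation), with 3 of 10 higher, also adjusted over the list alone, but not with fry (adjusted p = 0.0643), female arrays alone or without mutant_nacl replicate 4 (median -0.01), and the median was 0.27 without mutant_nacl replicate 1. Macrophage and dendritic cell markers fell (median log2 difference -0.16, adjusted p = 0.0342, and adjusted p = 0.53 with an estimated correlation), with 1 of 15 lower, also adjusted over the list alone. That call ended with fry (adjusted p = 0.156) and without any 1 of mutant_tam replicates 2 and 3 (medians -0.14 and -0.13) or mutant_nacl replicates 1, 2 and 3 (-0.15, -0.13 and -0.17), and the median was -0.10 without mutant_tam replicate 4. Of all genes 23.2% passed in this comparison.

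Of the markers of other tissue, all 12 smooth muscle markers fell, also adjusted over the list alone (median log2 difference -0.47, adjusted p = 1.11e-10, and adjusted p = 0.209 with an estimated correlation), among them Pcp4 (log2 difference -1.01, 2.01-fold, adjusted p = 2.72e-05) and Mylk (log2 difference -0.52, 1.43-fold, adjusted p = 0.000374). Enteric neuron and glia markers fell (median log2 difference -0.13, adjusted p = 0.00515, and adjusted p = 0.337 with an estimated correlation), with 5 of 11 lower and 1 higher, also adjusted over the list alone, and Vip, a neuropeptide gene, fell (log2 difference -0.40, 1.32-fold, adjusted p = 0.00396). The median of this list was -0.37 to -0.11 over the other settings. Fibroblast markers fell (median log2 difference -0.33, adjusted p = 0.00508, and adjusted p = 0.498 with an estimated correlation), with 7 of 12 lower and 1 higher, or 8 and 1 adjusted over the list alone, where Cd34 fell (log2 difference -0.53, 1.45-fold, adjusted p = 0.00361) and Pdgfra rose (log2 difference 0.41, 1.33-fold, adjusted p = 0.00626). Matrix and remodelling genes rose (median log2 difference 0.32, adjusted p = 3.72e-05, and adjusted p = 0.438 with an estimated correlation), with 13 of 23 higher and 2 lower, or 14 and 2 adjusted over the list alone, such as Timp1 (log2 difference 1.37, 2.58-fold, adjusted p = 3.91e-05) and Mmp9 (log2 difference 0.73, 1.66-fold, adjusted p = 0.000545). Mmp9 is also on the neutrophil list, which rose (median log2 difference 0.78). Which cells the matrix genes were read from was not tested.

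The remaining 17 lists did not pass against mutant NaCl. Adjusted p was 0.278 for stem cell and Wnt target, 0.906 for enteroendocrine, 0.199 for tuft cell, 0.106 for inflammasome and IL-1 family, 0.812 for IL-17 and IL-22, 0.122 for type 2 immunity, 0.239 for p53 and 0.203 for xenobiotic response genes. Among cell types it was 0.906 for squamous, 0.749 for endothelial, 0.122 for T cell and NK cell, 0.278 for B cell, 0.906 for eosinophil, 0.315 for mast cell, 0.197 for adipocyte, 0.937 for red blood cell and 0.331 for skeletal muscle markers. The eosinophil list had a median of 0.06 and a mean of -0.04 with the test up, and the squamous list a median of 0.07 and a mean of 0.00. Of the 17 lists that passed, the absorptive colonocyte list also passed with an estimated correlation, and 4 of the 35 ways to divide the 8 arrays into groups of 4, the real one included, gave at least 17 list calls. With the lowest 50% of genes left out, the hemidesmosome, goblet cell, wound, chemokine, plasma cell, macrophage and neutrophil lists lost their calls, the chemokine and macrophage lists with the lowest 25% left out as well.

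**Figure D2:**
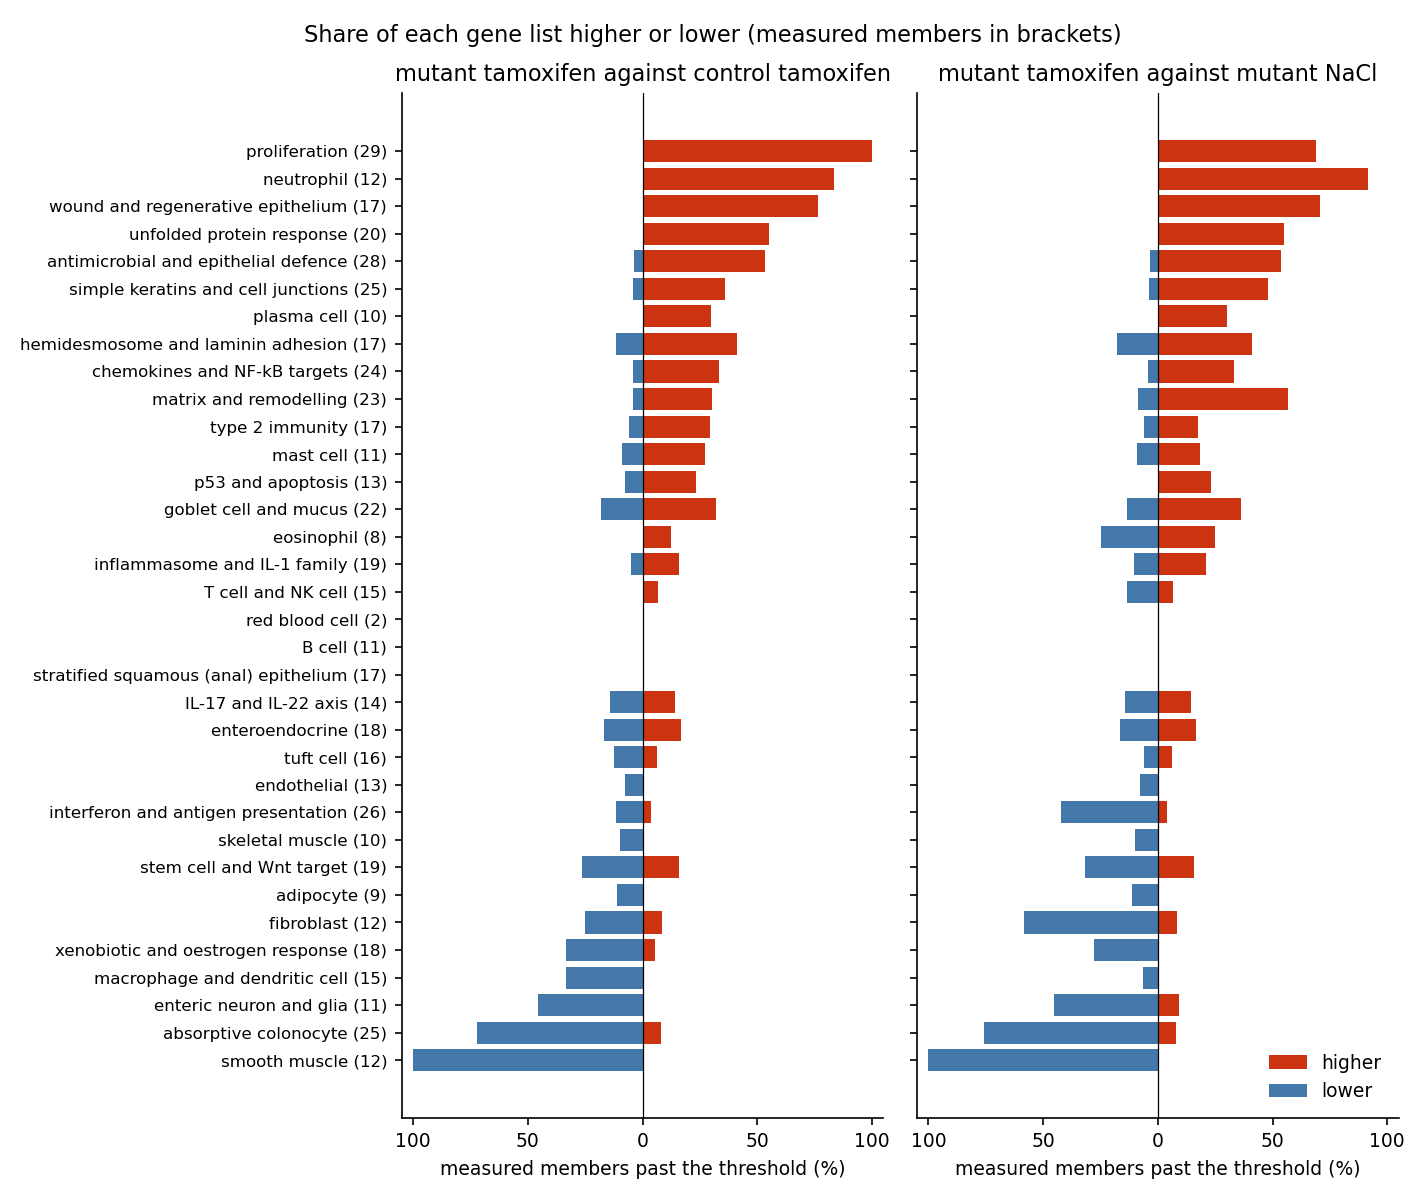
Share of the measured members of each of the 34 lists that were higher (red) or lower (blue) in the arrays labelled mutant tamoxifen, in percent, against the control tamoxifen arrays and against the mutant NaCl arrays. All 29 proliferation genes were higher in the comparison with the control arrays and 20 in the other, and all 12 smooth muscle markers were lower in both.

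Calls in both comparisons mark genes that differed from each reference group. There were 3526 such genes with the same direction, 1974 higher and 1552 lower, and 0 with opposite directions. They included Lrg1, Pla2g2a, Cwh43, Dhrs9 and Mfsd2a among the higher and Cyp2c55, Tgm3, Cyp2d12 and Naaladl1 among the lower. Independent lists of these lengths would share 322 and 251 genes. Both comparisons use the same 4 arrays labelled mutant tamoxifen. In 100 simulations all arrays were redrawn as unchanged groups, each gene independently of the others, and 0.01 genes were shared on average. Only 0.17 genes were called there in either comparison, so this count does not show how many shared calls come from using the same arrays. Across genes, which are not independent replicates, the log2 differences of the comparisons correlated at 0.881, against 0.435 in the simulation, and their covariance was 0.0693 against 0.00398. The simulation leaves out that genes vary together between arrays, so its values do not show how far these could range by chance. When the 4 arrays were divided between the comparisons, 2 to each, the 6 assignments gave 1423 to 1888 shared genes, correlations of 0.691 to 0.796 and covariances of 0.0601 to 0.0655. Without mutant_tam replicate 3 there were 1912 shared genes. A further 1389 genes passed against the control arrays and not against mutant NaCl, and 1108 the other way round. Of the 1389, 97.6% had the same sign in both comparisons.

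**Figure D3:**
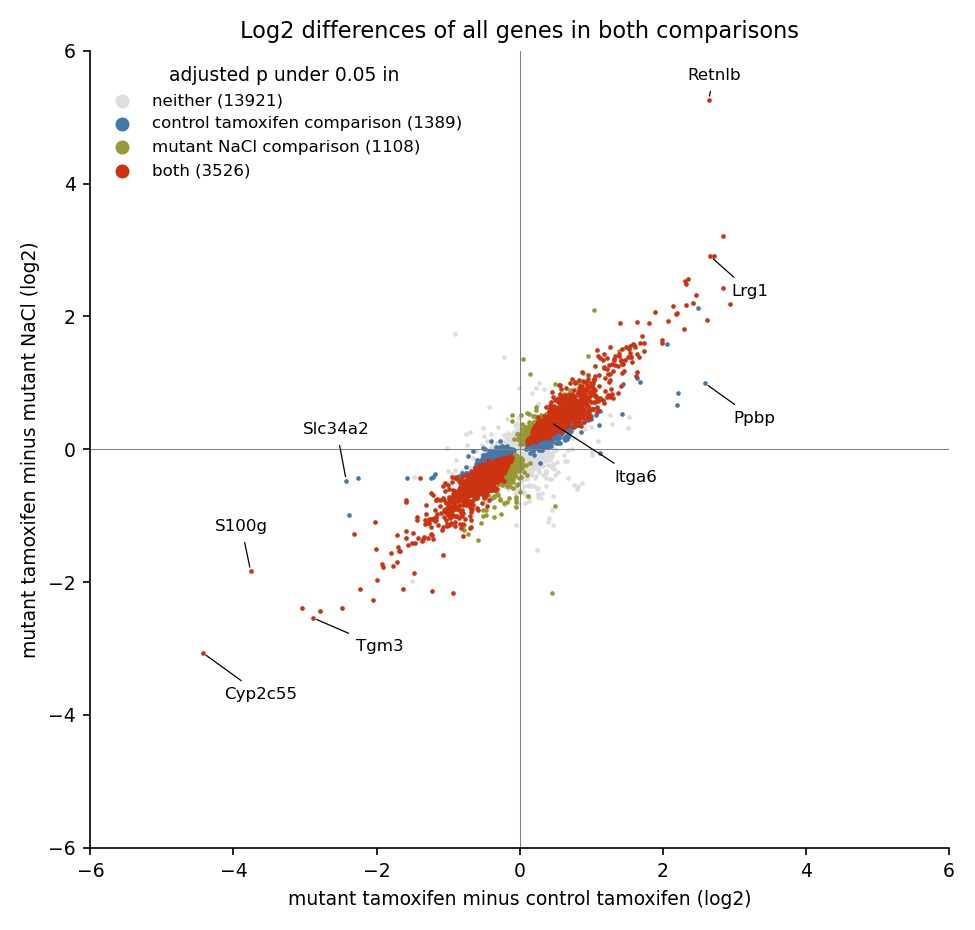
Log2 difference of each gene between the arrays labelled mutant tamoxifen and the control tamoxifen arrays (horizontal) and the mutant NaCl arrays (vertical), each point 1 gene. The 3526 genes past the threshold in both (red) had the same sign in both, and 1389 passed in the horizontal comparison alone (blue) and 1108 in the vertical one alone (olive).

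Against the mean of both reference groups, the arrays labelled mutant tamoxifen differed in 6040 genes, or 30.3% of those tested by limma, of which 3178 were higher and 2862 lower (3618 and 2331 with each array centred on its median). Itga6 was higher here as well (log2 difference 0.42, SE 0.076, adjusted p = 0.00215), against its label. Among the lists, 11 rose and 5 fell. The absorptive colonocyte list (median log2 difference -0.63, adjusted p = 8.56e-11, and adjusted p = 0.00592 with an estimated correlation), the smooth muscle list (median log2 difference -0.48, adjusted p = 1.1e-09, and adjusted p = 0.257 with an estimated correlation) and the proliferation list (median log2 difference 0.63, adjusted p = 1.4e-13, and adjusted p = 0.307 with an estimated correlation) were among the 16, and 9 of 100 regroupings of the arrays, the real one included, gave as many. Without mutant_tam replicate 3 the number of genes called was 3709. Values of one group lay wholly above those of the other for 22.2% of genes, where chance gives 0.606%, and for 37.4% against the control arrays (chance 5.71%) and 26.8% against mutant NaCl (chance 2.86%).

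**Figure D4:**
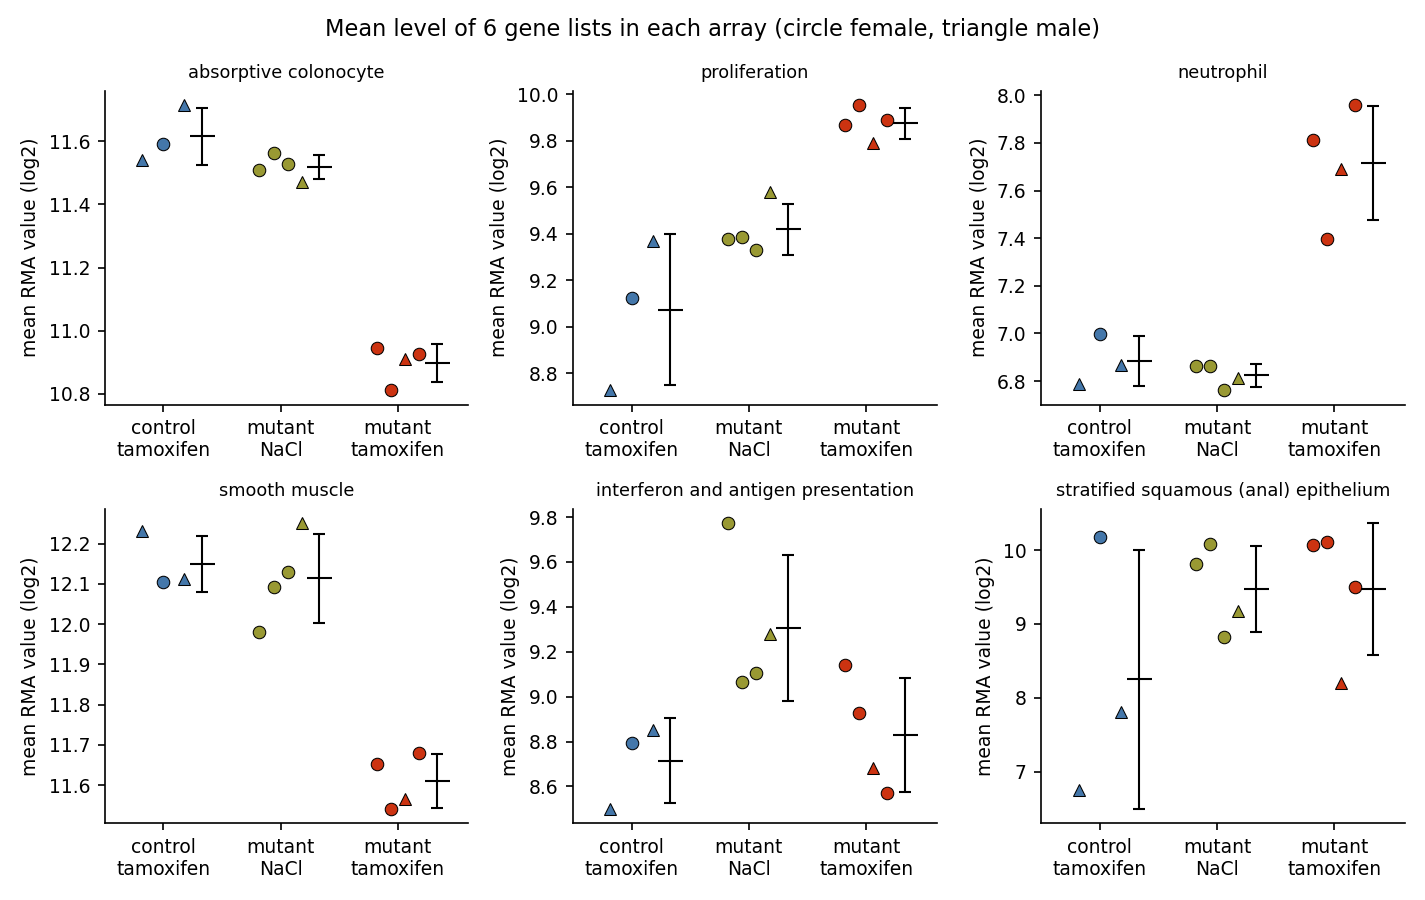
Mean log2 level of 6 lists in each of the 11 arrays, with a bar for the group mean with its SD. Smooth muscle markers lie at 11.54 to 11.68 in the arrays labelled mutant tamoxifen and at 11.98 to 12.25 in the others, while squamous markers vary within each group, from 6.76 to 10.18 in the control arrays.

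The mutant NaCl and control tamoxifen groups, neither of which should carry the deletion, differ in both genotype and gavage, and show the background of the other comparisons. No gene passed. The limma fit called 0 genes, with 1625 at an unadjusted p under 0.05 and 0 to 3 genes past the threshold in its other settings. The gene with the smallest p was S100g, lower in mutant NaCl by a log2 difference of -1.93 (adjusted p = 0.053), and it passed without mutant_tam replicate 2 (-1.89) or replicate 4 (-1.97), whose spread enters the shared variance. The next genes by p, none of them past the threshold, were Slc34a2 (-1.95, adjusted p = 0.396), Abcc2, an export pump for conjugates (-0.96, adjusted p = 0.396), Hpgds, a prostaglandin D synthase (-0.57, adjusted p = 0.396), Gpr141b (0.67, adjusted p = 0.396) and H2bc21 (-0.32, adjusted p = 0.396). Also among the 10 were the metallothionein gene Mt1 (-0.61, adjusted p = 0.399), Il18bp, which binds interleukin 18 (0.35, adjusted p = 0.399), Lynx1 (0.50, adjusted p = 0.399) and Xcr1, a chemokine receptor of dendritic cells (0.50, adjusted p = 0.399). Values of the groups did not overlap for 8.14% of genes, where chance gives 5.71%.

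As groups, 5 lists were higher in the mutant NaCl arrays and 1 was lower, although no member of any list passed over all genes and 29 of the 35 ways to divide these 7 arrays gave at least 6 list calls. Proliferation genes (median log2 difference 0.38, adjusted p = 1.58e-16, and adjusted p = 0.814 with an estimated correlation) and interferon and antigen presentation genes (median log2 difference 0.53, adjusted p = 1.02e-14, and adjusted p = 0.814 with an estimated correlation) were higher. The interferon list had 11 members higher adjusted over the list alone and the proliferation list 0. The proliferation median was 0.21 without control_tam replicate 1 and 0.23 without mutant_nacl replicate 4. T cell and NK cell markers (median log2 difference 0.23, adjusted p = 0.000415, and adjusted p = 0.903 with an estimated correlation) and B cell markers (median log2 difference 0.62, adjusted p = 0.000415, and adjusted p = 0.903 with an estimated correlation) were higher, but neither was past the threshold without control_tam replicate 2 (medians 0.05 and 0.08). Their medians were 0.11 and 0.31 without mutant_nacl replicate 1, and 0.46 and 1.28 without mutant_nacl replicate 4. Squamous epithelium markers were higher (median log2 difference 0.44, adjusted p = 0.00657, and adjusted p = 0.903 with an estimated correlation), but not past the threshold without control_tam replicate 1 (0.16) and reversed without mutant_nacl replicate 4 (-0.18). The squamous median was 1.42 without control_tam replicate 2 and 0.77 without mutant_nacl replicate 3. Goblet cell genes were lower (median log2 difference -0.13, adjusted p = 0.00761, and adjusted p = 0.903 with an estimated correlation), a call lost without control_tam replicates 2 (-0.11) or 3 (-0.13) or mutant_nacl replicate 4 (-0.04). None of the 6 lists passed with fry. The squamous, T cell and B cell lists also lost their calls with the lowest 50% of genes left out, the squamous list with female arrays alone, array weights, a squamous marker term or 1 control array, and the goblet cell list with no sex term. The other 28 lists did not pass, with adjusted p from 0.197 to 0.942.

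Sex, the other label that varied, separated 7 genes. Eif2s3y (4.45), Uty (3.69) and Kdm5d (2.68), which lie on the Y chromosome, were higher in males on the log2 scale. Xist, which is expressed from the inactive X chromosome, was lower in males (-6.31), as were Kdm6a, Eif2s3x and Kdm5c, X-linked genes known to escape inactivation. Without mutant_nacl replicate 3, 20 genes passed.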

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

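The tests of exchanged arrays and groups and of squamous marker levels, the fit with a squamous marker term and that with 1 control array were chosen after the results were seen, and the divisions of the arrays were fixed earlier.

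Itga6, the gene meant to be deleted, read higher in the arrays labelled mutant tamoxifen, by a log2 difference of 0.42 from control tamoxifen (not a call with female arrays alone, 0.30, or with 1 control array, 0.29) and 0.41 from mutant NaCl. Squamous epithelium, whose basal cells express Itga6, is argued against as the whole difference from control tamoxifen, which was 0.38 (SE 0.095) with the squamous marker level as a term. Against mutant NaCl the term tested nothing (0.41 with it), but the squamous levels argue against squamous epithelium as the whole difference, being 9.47 in each group (upper 95% limit of the difference 1.24), where the upper 95% limit of the slope of Itga6 on them needs 1.98 for the whole. Exchanged single arrays are argued against, since 0 arrays lay nearer to the mean profile of the other side, and exchanged whole groups only if the probes report the deletion, when 1 reference group should read lower in Itga6 than the other, and they differed by 0.0106 (SE 0.096). A part of the difference from squamous epithelium, probes outside the deleted part, with or without exchanged groups, and more Itga6 from cells that kept the gene stay open, and no biological explanation was tested. If another group held the deletion, it would differ from one without it in 0 genes, as mutant NaCl and control tamoxifen did. Then a group without the deletion would hold the 4915 and 4634 genes called in the arrays labelled mutant tamoxifen. Smooth muscle markers had a mean level of 11.54 to 11.68 in these arrays and 11.98 to 12.25 in all others. Whether the share of tissue other than squamous epithelium bears on Itga6 was not tested.

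A further pattern is that 1389 genes passed against control tamoxifen and not against mutant NaCl, while squamous markers differed widely among the 3 control arrays (6.76, 10.18 and 7.81). Of these genes, 97.6% had the same sign against mutant NaCl, with a median absolute log2 difference of 0.134. Between the reference groups 0 genes passed, so passing in 1 comparison alone does not mark a gene as specific to it. If squamous content made the differences of these genes from control tamoxifen, a term for it should shrink them. Their median absolute log2 difference from control tamoxifen was 0.262 without the term and 0.253 with it, a ratio of 0.966, and 799 of the genes still passed. These genes were chosen by their calls, which a gene that follows squamous levels within groups hardly gets, as 0 of 17 squamous markers passed. Genes called in both comparisons gave a ratio of 0.973. The ratio could thus hardly have fallen, and the test does not decide whether squamous content was the cause. Effects of tamoxifen or genotype that the groups share or lack stay open, as no array of wild-type mice given NaCl was analysed here.

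For the numbers of genes called with the mutant tamoxifen group, no other division counted gave as many as the real one. With 35 divisions the smallest share that can be reached is 1 of 35. In other divisions the real difference between groups adds to the spread, which lowers their counts. Of 35 divisions of the 7 arrays labelled mutant tamoxifen and control tamoxifen, 1, the real one, gave as many as 4915 genes, and the highest other gave 24. Against mutant NaCl it was 1 of 35, with 4634 genes and 0 in the highest other. Against both reference groups it was 1 of 100 regroupings, with 6040 genes and 13, and for genes called in both comparisons 1 of 100, with 3526 and 0. For sex it was 2 of 100, with 7 genes in the real division and more, 24, in another. Between mutant NaCl and control tamoxifen limma called 0 genes (1625 at an unadjusted p under 0.05) and the highest other division gave 5, and since all 35 give at least 0, the count of divisions tests nothing there.

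For the numbers of lists called with the preset correlation, chance cannot be excluded. Against control tamoxifen 7 of 35 divisions gave at least the real 15 lists (highest other 17), and against mutant NaCl 4 of 35 gave at least 17 (highest other 19). Against both reference groups 9 of 100 gave at least 16 (highest other 23), and for mutant NaCl against control tamoxifen 29 of 35 gave at least 6 (highest other 18). List calls made with the preset correlation alone are thus weaker evidence than the calls of their members. The absorptive colonocyte list also passed with an estimated correlation against each reference group, which these divisions did not count.

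In 9 of 140 groups of 4 arrays tested, 1 array lay apart from the others by a gap past the 95% critical value of Dixon's test, where chance gives about 1 in 20. Cwh43 was highest in mutant_tam replicate 4, at 11.29 against 10.82 to 10.86 (gap 0.911 of the range). Ddah1 was lowest in mutant_nacl replicate 1 (0.903), and Abcc2 was highest there (0.889). By mean level, mutant_tam replicate 4 was highest in simple keratins and cell junctions (0.898) and in the xenobiotic and oestrogen response list (0.870). Mutant_nacl replicate 4 was lowest in unfolded protein response genes (0.904) and in macrophage and dendritic cell markers (0.910). Enteroendocrine genes were highest in mutant_nacl replicate 3 (0.893), and adipocyte markers were lowest in mutant_tam replicate 3, at 7.21 against 7.80 to 7.89 (0.866).

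The 13759 transcript clusters that the annotation gives no single symbol also carried differences. Tested alone with limma, 672 passed against control tamoxifen (406 higher and 266 lower, 4.88%) and 459 against mutant NaCl (280 higher and 179 lower, 3.34%). Between the reference groups 0 passed, with 959 at an unadjusted p under 0.05.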

How the results depend on the processing

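The squamous term and the fit with 1 control array were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers shared between groups. The number of arrays limits all comparisons, and signal over background could not be judged from the summarised values.

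Itga6 kept its direction and call against mutant NaCl in all 25 settings run and against both reference groups in all 24. Against control tamoxifen it kept the call in 22 of 25, and not with female arrays alone (0.30), with 1 control array (0.29) or without mutant_tam replicate 3. With each array left out in turn it was 0.33 to 0.54. The absorptive colonocyte list passed in 26 of 26 settings against control tamoxifen and in 26 of 26 against mutant NaCl. Of the 20 named genes against control tamoxifen, Plet1 lost its call in 2 of 25 settings (female arrays alone and 1 control array), St8sia5 in 3, Ppbp in 11, Retnlb in 14 and AI506816 in 17, and against mutant NaCl Krtap15 in 19 of 23, while the others kept theirs. Over all values of named genes and list members, each counted once per setting, 2639 kept their call against control tamoxifen, 354 lost and 18 gained it, and against mutant NaCl 2716, 146 and 36. For lists the numbers were 349, 41 and 16, and 406, 36 and 11, and none of these calls changed sign.

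With female arrays alone, where the lone control array is assumed to vary like the other groups, fewer arrays gave 1385 genes against control tamoxifen, 3459 against both reference groups and 1208 in both comparisons. Between mutant NaCl and control tamoxifen, female arrays gave 14 lists, and the squamous list (-0.68) and the macrophage and dendritic cell list (0.13) changed sign. With 1 control array there were 1409 genes against control tamoxifen, 1294 in both comparisons and, between mutant NaCl and control tamoxifen, 13 lists, with the squamous list at -0.51. The lone control array of both fits has high squamous markers, which gives the squamous list that sign.

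Requiring a difference of at least 1.5-fold, a stricter rule, left 917 genes against control tamoxifen, 668 against mutant NaCl, 791 against both reference groups, 531 in both comparisons and 4 for sex. Without the lowest 50% of genes, lists past the threshold numbered 7 against control tamoxifen, 10 against mutant NaCl and 10 against both reference groups, and 4 genes differed by sex, as fewer genes were tested. With an estimated correlation 1 list passed against control tamoxifen, 1 against mutant NaCl, 1 against both reference groups and 0 between mutant NaCl and control tamoxifen, where fry also gave 0. With fry 14 lists passed against control tamoxifen, 17 against mutant NaCl and 20 against both reference groups. Genes between mutant NaCl and control tamoxifen numbered 3 with only the arrays of those groups, 1 without the lowest 50%, 1 after quantile normalisation again, 1 with array weights and 3 with the squamous term. S100g was among them each time, with Slc34a2 in the first and Abcc2 in the last. With the squamous term 4 genes differed by sex. When the arrays labelled mutant tamoxifen were divided between the comparisons, which leaves fewer samples to each, genes in both numbered 1458, 1888, 1480, 1799, 1423 and 1717.

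With each array left out in turn, genes numbered 2517 (without mutant_tam replicate 3) to 4685 against control tamoxifen, with 3031 without control_tam replicate 2. They numbered 3150 to 4924 against mutant NaCl, 3709 (without mutant_tam replicate 3) to 6079 against both reference groups and 1912 (the same array) to 3212 in both comparisons. Between mutant NaCl and control tamoxifen there were 0 to 3 genes, with 1 without mutant_tam replicate 2 or mutant_nacl replicate 1, 2 without mutant_tam replicate 4 and 3 without control_tam replicate 2. Lists there numbered 5 to 10 (10 without control_tam replicate 1), and the squamous list ranged from -0.18 (without mutant_nacl replicate 4) to 1.42. For sex there were 5 to 20 genes, 20 without mutant_nacl replicate 3. Except where said, the cause was not tested.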

Other observations

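The 5 gene lists described here were chosen after single members had been seen, as was the test of the time of day, so their p-values are not independent evidence. Signs follow the labels, against which Itga6 went.

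Genes of calcium and phosphate uptake were lower in the arrays labelled mutant tamoxifen. Against both reference groups S100g (-2.80), the calcium channel gene Trpv6 (-1.80), the magnesium channel gene Trpm6 (-1.75), the phosphate transporter genes Slc34a2 (-1.45) and Slc20a1 (-1.05) and the vitamin D receptor gene Vdr (-1.12) fell on the log2 scale. Slc34a2 did so mainly against control tamoxifen (-2.42) and did not pass against mutant NaCl (-0.47, adjusted p = 0.296). Of 14 genes measured, 8 were lower against control tamoxifen (median -0.31, adjusted p = 3.19e-05 over 5 such lists, and adjusted p = 0.0153 with an estimated correlation) and 5 against mutant NaCl (median -0.17, adjusted p = 0.000199 over 5 such lists, and adjusted p = 0.0266 with an estimated correlation). Mutant NaCl lay below control tamoxifen with no member past the threshold over all genes (median -0.14, adjusted p = 0.000215 over 5 such lists, and adjusted p = 0.0239 with an estimated correlation), and 4 members were lower adjusted over the list alone. S100g had group means of 11.3 in control tamoxifen, 9.61 in mutant NaCl and 7.77 in the arrays labelled mutant tamoxifen, and Cyp2c55 had 10.9, 9.61 and 6.55.

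Serine synthesis and amino acid import genes rose against mutant NaCl, with 12 of 17 higher and 2 lower (median 0.55, adjusted p = 4.98e-05 over 5 such lists, and adjusted p = 0.138 with an estimated correlation). The cystine transporter gene Slc7a11 (1.54), Psat1 (0.89), Mthfd2 (0.79) and Phgdh (0.55) were higher, and Slc1a5 (-0.45) and Cth (-0.43) lower. Against control tamoxifen 10 were higher and 2 lower (median 0.45, adjusted p = 4.6e-05 over 5 such lists, and adjusted p = 0.152 with an estimated correlation). Cholesterol synthesis genes were higher against control tamoxifen in 12 of 19 (median 0.60, adjusted p = 3.31e-06 over 5 such lists, and adjusted p = 0.29 with an estimated correlation) and against mutant NaCl in 1 (median 0.34, adjusted p = 0.0015 over 5 such lists, and adjusted p = 0.41 with an estimated correlation), and mutant NaCl lay above control tamoxifen without a member past the threshold (median 0.33, adjusted p = 2.54e-05 over 5 such lists, and adjusted p = 0.428 with an estimated correlation).

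Output and repressor genes of the circadian clock were lower in the arrays labelled mutant tamoxifen, with 10 of 11 lower against both reference groups (median -0.49, adjusted p = 1.61e-07 over 5 such lists, and adjusted p = 0.0453 with an estimated correlation) and against mutant NaCl (adjusted p = 0.0277 with an estimated correlation), and 9 against control tamoxifen, where the list lost its call with an estimated correlation (adjusted p = 0.076). Nr1d1 (-1.06), Ciart (-1.04), Dbp (-0.98) and Cry2 (-0.64) fell, and Per2 read -0.30 (adjusted p = 0.0714). Tissue collected at another time of day may account for this, and then Arntl, of the opposite phase, should have risen by 0.3 or more. Its difference was 0.10 (SE 0.121), short of that. By the rule set, only a fall of 0.3 or more would have counted against the time of day. The test could thus hardly reject it and leaves it open. Of the other genes of that phase, Nfil3 (0.63) and Cry1 (0.34) were higher and Clock was not (-0.02), and their list did not pass (adjusted p = 0.104, and adjusted p = 0.312 with an estimated correlation). A weaker clock in the tissue was not tested and cannot be told apart from the time of day, as collection times are not given in the sources used here.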
